A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

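The data were 7 arrays with 2 channels each, hybridised with total RNA from the budding yeast Saccharomyces cerevisiae sampled over a time course of growth on glucose. Per the labels, channel 1 of every array held RNA of a culture at 0.14 OD with 19 g/L glucose in the medium, the common reference. Channel 2 held RNA of the culture at 0, 9.5, 11.5, 13.5, 15.5, 18.5 or 20.5 h. Each time point was 1 array, and each array was put in its group by the time in its title. No label says whether the samples came from 1 culture flask or several. The p-values of the trend test whether its slope differs from 0, against the scatter about the line over 7 samples of one time course. They do not measure the spread between cultures. The test also treats the 7 arrays as independent, which neighbouring samples of a time course need not be, so its standard errors and p-values may be too small. The labels also give each array its own lot, so array lot and time point cannot be told apart.

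Per the labels, the software used for the arrays was ScanAlyze version 2.41. Background correction, dye normalization, the filter on spots and the reason for blank cells are not given in the sources used here. The deposited values are log ratios of the 2 channels, and scanner intensities were not used here. The logarithm was taken as log2 from the values themselves. Large ratios of small whole numbers should pile up at fixed places, and 156 values lay at the 62 places for log2 against 110.25 interpolated from neighbouring places. For the natural log the figures were 268 against 265.64, and for log10 they were 194 against 196.58. The direction of the ratio is called likely, not certain, because neither the labels nor the file name the dyes. It was taken as culture over reference from the channel order in the labels and from what is known of the study. With that sign, 8 genes that textbooks give as glucose-repressed had a median of 3.49 at 20.5 h, and 101 ribosomal protein genes had a median of -1.90. Textbook knowledge of such genes rests partly on experiments of this kind, so these medians are not independent evidence of the direction.

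The table held 6400 probes, of which 5548 had 1 gene symbol, 0 had several and 852 had none. All 5548 were matched by Entrez gene ID to a RefSeq table of the yeast genome, which changed 0 symbols. The build behind the arrays is not given in the sources used here, so no coordinates are printed. The arrays had between 6048 and 6342 values. The medians of the deposited values were -0.001, 0.027, 0.018, -0.007, -0.033, 0.216 and 0.185 from 0 h to 20.5 h, and whether the authors centred the arrays is not stated. Each array was centred on its median over the probes with a value. Spots of one gene were averaged, which affected 75 genes. Of 5470 genes, 4807 had a value on all 7 arrays and entered the tests, and 663 were left out for a blank. A table of ratios holds no signal level. The SD between spots of one gene ranged from 0.19 at 13.5 h to 0.45 at 18.5 h on the log2 scale.

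The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes), a regression of the centred log2 ratio on the share of the starting glucose consumed. The coefficient is the fitted log2 change from 19 to 0 g/L glucose, with 5 residual degrees of freedom, 5.46 prior degrees of freedom and a median standard error of 0.24. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. On 4807 simulated genes the same test recovered 56 of 100 genes given a change of 1 on the log2 scale and 93 of 100 given a change of 2, with 0 wrong signs and 4 unchanged genes called. The simulated changes were straight lines in glucose with independent noise, and most genes were left unchanged. These rates need not hold for changes of another shape or for errors shared within an array. Time, OD and glucose moved together over the course and cannot be told apart by the design.

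The 24 gene lists were fixed before the data were examined, from textbook yeast physiology. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Fry was run beside it, which tests whether the genes of a list move one way on balance and does not compare the list with other genes. Lists defined by a name pattern caught some genes that are not members by function: RPP1 among the ribosomal proteins, MRP8 among the mitochondrial ribosomal proteins, and RPN4 and RPN14 among the proteasome genes. For single arrays, medians of lists were given with their percentile among 10000 random lists of the same size, not matched on expression.

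Genes were named by a rule fixed before the data were examined. It took the 12 genes with the largest fitted change in each direction among those that passed with the same sign on the 18.5 h and 20.5 h arrays. It also took up to 4 members with the largest fitted change from each list, the 5 largest differences in each direction between 18.5 h and 20.5 h, and 5 genes with large values at 13.5 h or 15.5 h that were under 2-fold at 20.5 h. A set of 12 genes was always included. Other genes named to explain a count, such as the members of a list that did not pass, were chosen after their values were seen. Genes with near-identical copies, such as TDH1 to TDH3, HXT6 and HXT7, ADH1 and ADH2, the paired ribosomal protein genes and the histone genes, are uncertain because such probes can hybridise to both copies.

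The alternatives planned before the data were examined were values as deposited, genes with at least 5 values, hours or log2 OD as the predictor, 2 glucose levels, robust eBayes, each spot tested alone, other thresholds, subtraction of the 0 h array, and leaving out each array in turn. Leaving out the 0 h and 9.5 h arrays together, and centring within runs of 40 consecutive probe IDs, were added after seeing the data. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.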

Results

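Gene expression was followed in budding yeast as the culture used up its glucose, a passage known as the diauxic shift, in which cells turn from fermenting glucose to respiring the ethanol they have made. Over the 7 time points the culture grew from 0.14 to 7.3 OD while glucose in the medium went from 19 to 0 g/L. Glucose stood at 18.7 g/L at 9.5 h, 17.6 at 11.5 h, 14 at 13.5 h, 7.5 at 15.5 h and 0.2 at 18.5 h. Each time point was compared on 1 array with a reference of the 0.14 OD culture, and there were no replicates. Values are log2 ratios of culture over reference, a direction that is likely but not stated by the labels, and each array was centred on its median. A value of 1 is 2-fold higher than the reference.

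The first question was how far expression departed from the reference at each time. At 13.5 h genes well above the reference included the glycogen synthase genes GSY1 and GSY2, at 2.11 and 2.10 at 13.5 h, the phosphoglucomutase gene PGM2 at 2.01, the hexose transporter gene HXT6 at 2.14, and HSP12, which encodes a small stress protein, at 1.77. By 18.5 h the ribosomal protein genes had a median of -1.46, after 0.05 at 15.5 h, and 89 of 107 were at least 2-fold below the reference. Genes of the tricarboxylic acid (TCA) cycle had medians of 0.84 at 13.5 h, 1.24 at 15.5 h, 1.87 at 18.5 h and 2.55 at 20.5 h. Genes of the glyoxylate cycle and gluconeogenesis, which build sugars from 2-carbon compounds, had a median of 0.30 at 15.5 h and 2.64 at 20.5 h.

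Of 4807 genes, 37 lay at least 2-fold from the reference at 0 h, 92 at 9.5 h, 42 at 11.5 h, 106 at 13.5 h, 273 at 15.5 h, 1133 at 18.5 h and 1077 at 20.5 h. The lower count at 11.5 h than at 9.5 h depends on the baseline. Relative to the 0 h array the counts were 58 at 9.5 h, 153 at 11.5 h and 176 at 13.5 h. At 15.5 h 172 genes were higher and 101 lower, at 18.5 h 572 were higher and 561 lower, and at 20.5 h 527 were higher and 550 lower. With the values as deposited the split was 834 higher and 414 lower at 18.5 h, and 715 higher and 439 lower at 20.5 h. The 0 h array, with the same label in both channels, gives the background, with an SD of 0.28 and all 37 genes on the low side. It may understate the background of the late arrays. The SD between spots of one gene was 0.21 at 0 h, 0.45 at 18.5 h and 0.36 at 20.5 h. At 9.5 h 24 genes were higher and 68 lower, and the 24 came down to 4 after centring within runs of 40 probe IDs, a setting chosen after seeing the data. The 0 h and 9.5 h arrays correlated with each other across genes (r = 0.64), while the 0 h and 18.5 h arrays had r = -0.29. Genes are not independent replicates, and with 1 array per time point no p-value is given for these counts.

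**Figure D1:**
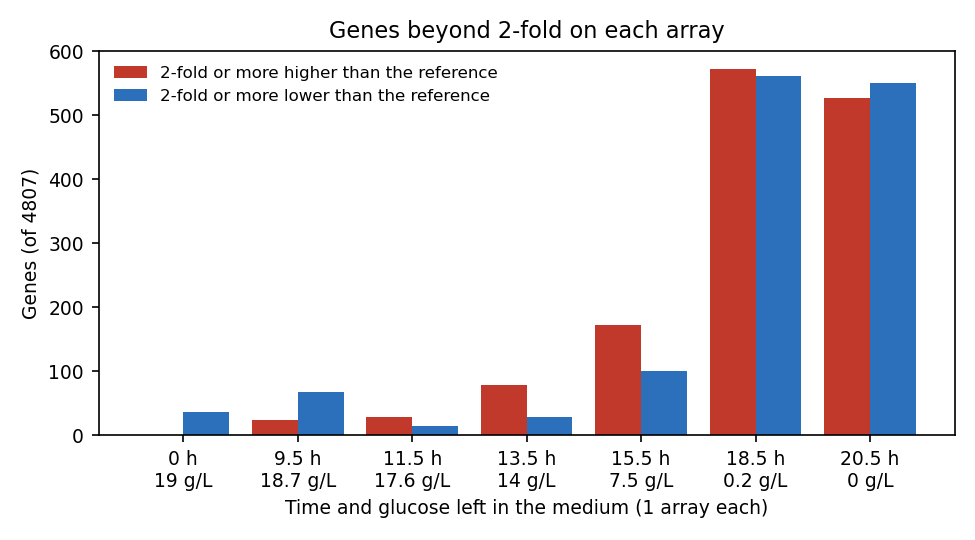
Number of genes at least 2-fold higher (red) or lower (blue) than the reference on each of the 7 arrays, of 4807 genes with a value on every array, with the time and the glucose left in the medium under each pair of bars. The counts were 0 higher and 37 lower at 0 h and 572 higher and 561 lower at 18.5 h, with 1 array per time point and no error bars.

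The main comparison asked which genes changed as glucose was consumed. Of the measured genes, 15 of 15 in the respiratory chain, 13 of 14 in the TCA cycle, 13 of 15 for glycogen and trehalose and 11 of 13 heat shock genes rose, while 103 of 107 ribosomal protein genes and 15 of 17 for ribosome biogenesis fell. As lists these passed at the preset correlation of the camera test, and with an estimated correlation 0 of the 24 lists did (lowest adjusted p 0.154). The citrate synthase gene CIT1 (YNR001C) rose by 2.67 ± 0.27 (SE, 7 arrays; adjusted p = 1.54e-04), which is 6.37-fold, and the ribosomal protein gene RPL17B (YJL177W) fell by 2.36 ± 0.27 (adjusted p = 2.50e-04). In all, 936 genes rose and 913 fell over the range from 19 to 0 g/L (limma), with a median size of 1.13 among the genes that rose and 1.17 among those that fell. Of these, 365 and 386 were at least 2-fold from the reference on both late arrays, and 323 and 288 on neither. As deposited, without centring, the split was 1223 genes higher and 708 lower, where the fitted change of the median gene was 0.20 against 0.02 after centring. Hours in place of glucose gave 266 higher and 233 lower, and log2 OD gave 597 and 512. Without the 18.5 h array 593 genes rose, and without both the 0 h and 9.5 h arrays, a setting chosen after seeing the data, 372 rose and 429 fell.

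Respiratory genes rose together. All 15 measured genes of the respiratory chain rose, with a median fitted change of 1.93, led by COX13 (YGL191W), a cytochrome c oxidase subunit, at 2.55 ± 0.22, and QCR7, a subunit of the cytochrome bc1 complex, at 2.48 ± 0.21. The camera test gave an adjusted p of 1.43e-09, and adjusted p = 0.167 with an estimated correlation. Of 14 TCA cycle genes 13 rose, among them the malate dehydrogenase gene MDH1 at 2.73 ± 0.20 and the succinate dehydrogenase genes SDH4 at 2.70 ± 0.24 and SDH2 at 2.49 ± 0.24. LSC1, a succinyl-CoA ligase subunit, did not pass, with a fitted change of -0.20 ± 0.27. The list had an adjusted p of 5.98e-08 (camera), and adjusted p = 0.154 with an estimated correlation. All 10 measured genes of the mitochondrial ATP synthase rose, such as ATP20 at 1.92 ± 0.21 and ATP7 at 1.67 ± 0.21, with a camera adjusted p of 2.28e-06, and adjusted p = 0.154 with an estimated correlation. Counts adjusted over the list alone were again 15, 13 and 10. Without the 0 h and 9.5 h arrays 13 respiratory chain, 11 TCA cycle and 6 ATP synthase genes rose, adjusted over all genes.

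Genes for growth on ethanol and other poor carbon sources rose in part. Of 12 measured genes of the glyoxylate cycle, gluconeogenesis and 2-carbon use, 9 rose, and 10 rose and 1 fell when adjusted over the list alone. JEN1 (YKL217W), the lactate and pyruvate transporter, rose by 3.88 ± 0.55, ACS1 (YAL054C), an acetyl-CoA synthetase, by 3.34 ± 0.68, and SFC1, a mitochondrial succinate and fumarate carrier, by 2.95 ± 0.71. The camera adjusted p of the list was 2.82e-04, and adjusted p = 0.209 with an estimated correlation. The isocitrate lyase gene ICL1 (YER065C) did not pass (2.05 ± 0.81, adjusted p = 0.0691; without the 18.5 h array it passed at 3.36, adjusted p = 0.0125), nor did YAT1, a carnitine acetyltransferase gene (0.07 ± 0.20), or ADH2, the alcohol dehydrogenase gene for ethanol use (-0.73 ± 0.32), whose near-identical copy is ADH1. Much of the rise lay in the last array: without it ACS1 was fitted at 1.95, SFC1 at 1.63 and ICL1 at 0.25, and 6 genes of the list rose. The list had a median of -0.37 on the 0 h array, and without the 0 h and 9.5 h arrays 5 of its genes rose. Of 10 genes of peroxisomal fatty acid oxidation 6 rose, 7 when adjusted over the list alone, among them SPS19 at 1.27 ± 0.21, ECI1 at 1.42 ± 0.28 and POT1, the thiolase gene, at 1.54 ± 0.41. That list had a camera adjusted p of 0.00159, and adjusted p = 0.250 with an estimated correlation. Its median was -0.22 at 0 h, POT1 stood at -1.82 at 0 h and 0.50 at 20.5 h and did not pass without the 18.5 h array (adjusted p = 0.0690) or the 20.5 h array (adjusted p = 0.0608), and 3 genes rose without the 20.5 h array and 2 without the 0 h and 9.5 h arrays.

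Genes of glycolysis and ethanol fermentation fell in part. Of 14 measured genes 8 fell and 6 did not pass, and the count adjusted over the list alone was also 8. The pyruvate kinase gene CDC19 (YAL038W) fell, at -1.99 ± 0.30, as did the pyruvate decarboxylase genes PDC1 (YLR044C) at -1.70 ± 0.30 and PDC5 at -1.70 ± 0.22, and the phosphofructokinase gene PFK2 at -1.36 ± 0.28. The list had a camera adjusted p of 1.64e-04, and adjusted p = 0.301 with an estimated correlation. The genes that did not pass were TPI1, TDH1, TDH2, TDH3, PGK1 and ENO1, with PGK1 at -0.53 ± 0.30 and ENO1 at -0.11 ± 0.19. Without the 20.5 h array 5 genes of the list fell.

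The machinery of protein synthesis fell broadly. Of 107 measured genes in the cytosolic ribosomal protein list 103 fell, 105 when adjusted over the list alone, with a median of -1.79, and examples were RPS20 at -2.44 ± 0.43, RPL8B at -2.42 ± 0.51 and the stalk protein gene RPP0 (YLR340W) at -2.59 ± 0.35. The camera adjusted p was 2.17e-27, and adjusted p = 0.234 with an estimated correlation. The 4 that did not pass were RPL17A (0.11 ± 0.20), RPP2A (-1.27 ± 0.47), RPS27B (-0.85 ± 0.34) and RPP1 (-0.30 ± 0.20), the last of which encodes a subunit of ribonuclease P and entered by its name. RPP2A passed without the 15.5 h array (-1.40, adjusted p = 0.0238) or the 18.5 h array (-1.81, adjusted p = 0.0350) and was at -0.31 without the 20.5 h array. Of 17 ribosome biogenesis genes 15 fell, 16 when adjusted over the list alone, with NOP58 (YOR310C), a nucleolar protein of small RNA particles, at -2.61 ± 0.37 and CBF5, the pseudouridine synthase, at -2.30 ± 0.30. That list had a camera adjusted p of 3.70e-09, and adjusted p = 0.159 with an estimated correlation. Of 14 genes of RNA polymerases I and III 11 fell, also 11 when adjusted over the list alone, and 6 without the 0 h and 9.5 h arrays. RPA34 led them at -1.87 ± 0.30, and the list had a camera adjusted p of 1.45e-05. It had adjusted p = 0.154 with an estimated correlation. Of 16 aminoacyl-tRNA synthetase genes 15 fell, by either adjustment including that adjusted over the list alone, with MES1 at -2.59 ± 0.32 and ILS1 at -2.06 ± 0.28, while DPS1 stood at -0.26 ± 0.22. The camera adjusted p was 9.26e-09, and adjusted p = 0.183 with an estimated correlation. Of 16 translation factor genes 14 fell, and 16 when adjusted over the list alone, among them TEF4 at -2.18 ± 0.30 and EFB1 at -2.02 ± 0.23 (camera adjusted p = 5.03e-08). It had adjusted p = 0.187 with an estimated correlation.

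Mitochondrial ribosomal protein genes rose in part. Of 52 measured, 26 rose, 27 when adjusted over the list alone, and 0 fell, with a median of 0.67 and examples MRPL16 at 1.52 ± 0.18 and MRPL25 at 1.21 ± 0.21. The camera adjusted p was 3.08e-06, and adjusted p = 0.252 with an estimated correlation. The largest fitted change, 1.95 ± 0.30, was that of MRP8, which is not a ribosomal protein and entered by its name. Leaving out 1 array gave between 11 genes risen, without the 18.5 h array, and 29, without the 15.5 h array, with 12 without the 0 h array and 13 without the 9.5 h array, and 3 without both of the latter.

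Genes for reserve carbohydrates and stress proteins rose for the most part. Of 15 genes of glycogen and trehalose metabolism 13 rose, also 13 when adjusted over the list alone, with GSY1 (YFR015C) at 3.31 ± 0.45, the branching enzyme gene GLC3 at 2.80 ± 0.30 and GSY2 at 2.77 ± 0.36. GPH1, the glycogen phosphorylase gene, was at 0.26 ± 0.30 and TPS3 at 0.40 ± 0.25. For the list camera gave an adjusted p of 1.53e-07, and adjusted p = 0.154 with an estimated correlation. Of 13 heat shock and chaperone genes 11 rose and YDJ1 fell by 0.59 ± 0.20, by the adjustment over all genes and adjusted over the list alone. The call of YDJ1 held when the 11.5 h or 15.5 h array was left out and not when any other was. Among those that rose were HSP12 (YFL014W) at 3.35 ± 0.27, HSP42 at 3.24 ± 0.29 and HSP26 at 3.09 ± 0.24. SSA1, a cytosolic Hsp70 gene, was at -0.19 ± 0.20. As a list they had a camera adjusted p of 2.99e-06, and adjusted p = 0.154 with an estimated correlation. Of 9 antioxidant genes 7 rose, 8 when adjusted over the list alone, among them GPX1 (YKL026C), a glutathione peroxidase, at 3.39 ± 0.35, the catalase gene CTT1 at 3.30 ± 0.29 and the peroxiredoxin gene PRX1 at 2.95 ± 0.33. In the camera test the list had an adjusted p of 4.28e-05, and adjusted p = 0.187 with an estimated correlation. Of 8 genes of vacuolar proteases and autophagy 6 rose, also 6 when adjusted over the list alone, led by ATG8 at 2.58 ± 0.19 and the aminopeptidase gene APE1 at 2.17 ± 0.30 (camera adjusted p = 9.54e-04). It had adjusted p = 0.154 with an estimated correlation.

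Transporter and regulator genes went both ways. Of 13 genes of hexose transport and glucose sensing 6 rose and 2 fell, 7 and 3 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.222). Without the 0 h and 9.5 h arrays 1 rose and 1 fell. HXT6 rose by 1.72 ± 0.39, HXT7 (YDR342C) by a fitted 2.83-fold and MTH1, a glucose-signalling repressor gene, by 1.93 ± 0.21. HXT2 fell by 1.68 ± 0.19 and HXT1, a low-affinity transporter gene, fell by 0.58 ± 0.18 (adjusted p = 0.0282), a call that did not hold without the 0 h array (adjusted p = 0.0958), the 9.5 h array (0.0854), the 11.5 h array (0.0534) or the 20.5 h array (0.0667). Of 18 carbon regulator genes 6 rose and 3 fell, the same counts as adjusted over the list alone, with a camera adjusted p of 0.280, and without the 18.5 h array 0 fell while without the 0 h array 1 fell. HAP4 (YKL109W), the activator subunit of the complex that turns on respiratory genes, rose by 2.44 ± 0.33, the gluconeogenic activator gene SIP4 by 2.75 ± 0.51 (1.67 without the 20.5 h array) and ADR1 by 1.52 ± 0.30. HAP5 also passed, with a fitted 1.47 ± 0.34, but stood at -1.55 at 0 h, -1.96 at 9.5 h and 0.02 at 20.5 h. TUP1 (YCR084C), a general corepressor gene, fell by 0.79 ± 0.21 (adjusted p = 0.0148), which did not pass without the 0 h array (adjusted p = 0.0568) or the 18.5 h array (0.0849). MSN2, at -1.25 ± 0.28 (adjusted p = 0.00637), and HAP1, at -0.77 ± 0.23 (adjusted p = 0.0244), also fell. The glucose repressor gene MIG1 (0.22 ± 0.31) and the oxidative stress regulator gene YAP1 (0.11 ± 0.21) did not pass.

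Genes of the cell cycle and of biosynthesis fell in part. Of 13 genes of the G1/S transition and DNA replication 6 fell, 8 when adjusted over the list alone, led by the ribonucleotide reductase gene RNR1 at -1.72 ± 0.23, with a camera adjusted p of 0.00462. It had adjusted p = 0.209 with an estimated correlation, and without the 9.5 h array 3 fell while without the 15.5 h array 9 fell. Without both the 0 h and 9.5 h arrays 1 fell. Of 13 amino acid biosynthesis genes 6 fell, also 6 when adjusted over the list alone, among them ILV5 at -2.27 ± 0.33 and ASN1 at -1.53 ± 0.27. Leaving out 1 array gave 4 to 8 fallen, and 2 fell without the 0 h and 9.5 h arrays. The list had a camera adjusted p of 0.0159. It had adjusted p = 0.187 with an estimated correlation. Of 9 purine biosynthesis genes 4 fell, 6 when adjusted over the list alone, including the inosine monophosphate dehydrogenase genes IMD2 at -2.31 ± 0.31 and IMD3 at -2.30 ± 0.29, with a camera adjusted p of 0.00326. It had adjusted p = 0.373 with an estimated correlation, and 7 fell without the 0 h array or without the 15.5 h array. Among 8 core histone genes HTB1 passed (-0.76 ± 0.24, a call lost without the 0 h, 9.5 h, 13.5 h, 18.5 h or 20.5 h array), 0 passed when adjusted over the list alone, and the list did not (camera adjusted p = 0.222), while 5 histone genes fell without the 15.5 h array. Of 31 genes matched as proteasome genes 5 rose, 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0609), with 2 genes risen without the 18.5 h array. Its largest fitted changes were those of RPN4, the transcription factor of proteasome genes, at 1.54 ± 0.34 and RPN14, an assembly chaperone, at 1.21 ± 0.26. Genes of meiosis and sporulation, another cell state, did not pass as a list (camera adjusted p = 0.247), with 2 of 10 risen and 1 fallen, also when adjusted over the list alone. Those 2, SPO11 at 1.47 ± 0.32 and DMC1 at 1.34 ± 0.34, stood at -0.84 and -0.73 at 0 h, DMC1 did not pass without the 18.5 h array (adjusted p = 0.0644), the list had a 0 h median of -0.34, and without the 0 h and 9.5 h arrays 0 of the list passed.

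Among single genes, the largest rise with the same sign on both late arrays was that of NQM1 (YGR043C), a transaldolase, at 4.02 ± 0.47 (adjusted p = 2.59e-04). It was followed by YNL194C, a membrane protein gene, at 3.89 ± 0.45, JEN1, the mitochondrial outer membrane protein gene OM45 (YIL136W) at 3.66 ± 0.51, SOL4 (YGR248W), a 6-phosphogluconolactonase, at 3.62 ± 0.39, and the mitochondrial pyruvate carrier gene MPC3 (YGR243W) at 3.57 ± 0.50. The reticulon gene RTN2 at 3.54 ± 0.59 and SPG1 at 3.46 ± 0.65 came next. The largest fall was that of UTP5 (YDR398W), a gene of small ribosomal subunit assembly, at -3.79 ± 0.80, which was -2.02 without the 20.5 h array, where it stood at -5.67. RRP12 (YPL012W), which acts in the export of ribosomal subunits, was at -3.17 ± 0.27, SAM1 (YLR180W), an S-adenosylmethionine synthetase, at -3.05 ± 0.28, DBF2 (YGR092W), a kinase of mitotic exit, at -2.98 ± 0.24, and INA1 at -2.91 ± 0.33. HAS1, an RNA helicase of ribosome assembly, AAH1, the adenine deaminase, GPP1, a glycerol-phosphate phosphatase, and PWP1, a ribosome assembly factor, were at -2.84 ± 0.24, -2.80 ± 0.27, -2.64 ± 0.26 and -2.61 ± 0.33 in that order.

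After Benjamini-Hochberg adjustment 0 of the 24 lists passed with an estimated correlation, whose lowest adjusted p was 0.154, while 10 lists passed as higher and 9 as lower at the preset correlation. The estimated correlations rest on 5 residual degrees of freedom.

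**Figure D2:**
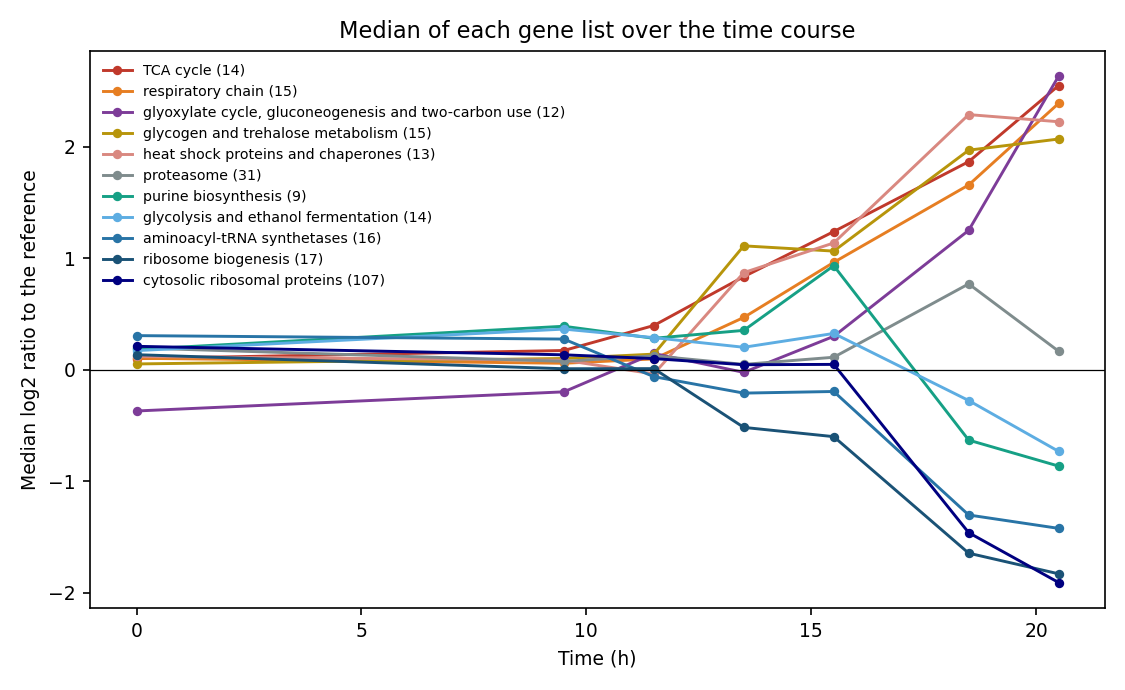
Median log2 ratio to the reference (vertical axis) of 11 of the 24 gene lists at each of the 7 times in hours (horizontal axis), with the number of genes of each list in brackets and 1 array per time point, so no error bars. The ribosomal protein median went from 0.05 at 15.5 h to -1.46 at 18.5 h, and the purine biosynthesis median from 0.94 to -0.63 over the same step.

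The step from 13.5 h to 18.5 h covers most of the glucose, from 14 to 0.2 g/L. JEN1 was higher by 3.55 at 18.5 h than at 13.5 h, NQM1 by 3.81, SPG1 by 3.76, GPX1 by 3.14 and CTT1 by 2.73, and RRP12 was different by -2.49, RPL8B by -2.21 and SAM1 by -2.13. The median difference was 1.54 for antioxidant genes, 1.22 for heat shock genes and 1.03 for TCA cycle genes, and it was -1.54 for ribosomal protein genes, -1.28 for ribosome biogenesis genes and -1.42 for purine biosynthesis genes. Among 10000 random lists the higher medians lay at the 100th percentile and the lower ones at the 0th. In all, 416 genes were at least 2-fold higher at 18.5 h than at 13.5 h and 431 at least 2-fold lower, or 696 and 275 with the values as deposited. Most of this difference arose after 15.5 h: from 13.5 h to 15.5 h 11 genes were 2-fold higher and 45 lower, and from 15.5 h to 18.5 h 478 were higher and 448 lower. Each of these steps compares 1 array with 1 array and has no test.

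The last step, from 18.5 h to 20.5 h, took glucose from 0.2 to 0 g/L. Genes of gluconeogenesis and the glyoxylate cycle stood out in it. PCK1 (YKR097W), the phosphoenolpyruvate carboxykinase gene, was at 0.34 at 18.5 h and 4.10 at 20.5 h, a difference of 3.76. ICL1 was at 0.46 and then 4.17, 17.99-fold above the reference, and FBP1 (YLR377C), the fructose-1,6-bisphosphatase gene, at 0.45 and then 4.09. SFC1 differed by 2.44 and ACS1 by 2.53, and the regulator gene SIP4 by 2.27. The value of ICL1 was the highest at 20.5 h among the 4807 genes. JEN1 at 4.064, SFC1 at 4.055 and ACS1 at 4.054 lay close under it, as did PCK1 and FBP1. Whether large ratios were held to a limit on that array was not tested, so these differences may not rank the genes. The 12 measured genes of the glyoxylate cycle, gluconeogenesis and 2-carbon use, which leave out PCK1, had a median difference of 0.78, at the 100th percentile of random lists. PCK1 had a blank at 11.5 h and was outside the main test. With at least 5 values required it was fitted at 2.33 ± 0.94 (adjusted p = 0.0773), and FBP1, which passed at 2.30 ± 0.81 (adjusted p = 0.0441), was fitted at 0.52 without the 20.5 h array (adjusted p = 0.110) and also did not pass without the 0 h, 9.5 h, 11.5 h or 13.5 h array (adjusted p from 0.0636 to 0.0819), while without the 18.5 h array it passed at 3.58 (adjusted p = 0.0105).

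Over the same step, 156 genes were at least 2-fold higher and 98 at least 2-fold lower. Besides ICL1 and FBP1 the largest increases among genes with a value on all 7 arrays were those of PYC1, a pyruvate carboxylase gene, at 2.95, IRC15 at 2.65 and NOP2, a ribosome biogenesis gene, at 2.63. The largest decreases among them were those of UTP5 at -3.52, IRC3 at -1.87, the phosphatidylinositol synthase gene PIS1 at -1.81, the ribosomal stalk gene RPP2A at -1.79 and the hexokinase gene HXK1 at -1.75. Single spots stand behind these 10 genes. NOP2 was at -2.41 at 18.5 h and 0.22 at 20.5 h, and its fitted change of -0.83 ± 0.59 became -2.07 without the 20.5 h array, where it passed (adjusted p = 0.00204), and 0.15 without the 18.5 h array. The respiratory chain median was 0.59 higher and that of ribosomal protein genes differed by -0.45. Proteasome genes had a median of 0.77 at 18.5 h and 0.17 at 20.5 h, with 29 of 31 genes lower at 20.5 h, and mitochondrial ribosomal proteins went from 0.89 to 0.40.

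**Figure D3:**
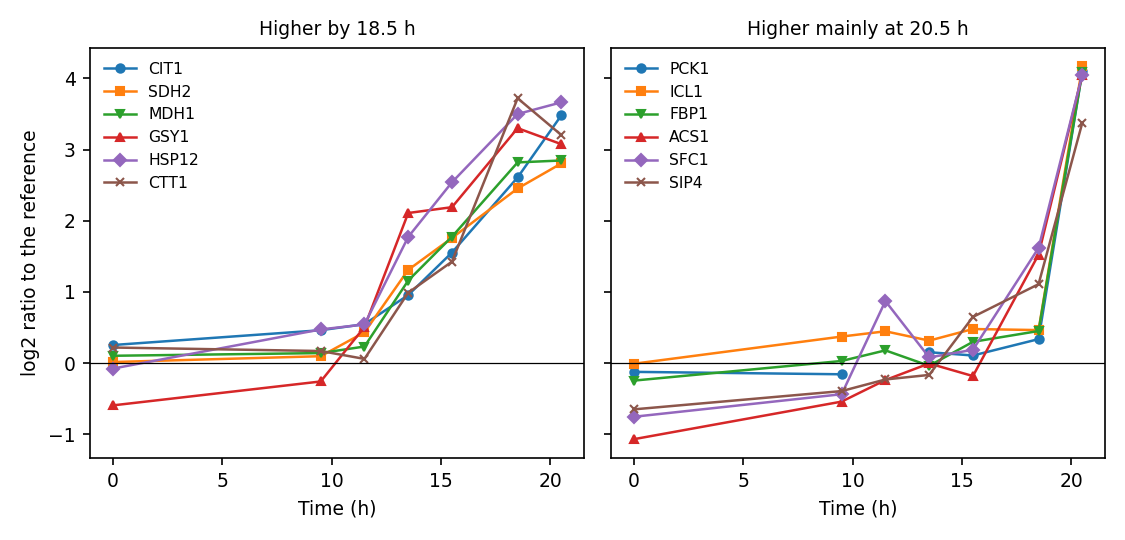
Log2 ratio to the reference (vertical axis) against time in hours (horizontal axis) for 12 named genes, 1 array per time point and no error bars. CIT1, SDH2, MDH1, GSY1, HSP12 and CTT1 (left) stood above 2 at 18.5 h, while PCK1, ICL1 and FBP1 (right) stood under 0.5 at 18.5 h and above 4 at 20.5 h. The genes were picked after their values were seen, and the line of PCK1 is broken at its blank at 11.5 h.

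The 18.5 h and 20.5 h arrays share the reference, which adds to their likeness. Across genes they correlated at r = 0.84, where simulated unchanged arrays with a shared reference gave 0.50. That 0.50 is not a firm baseline, since the real 0 h array, with the same reference, had r from -0.29 to 0.64 with the other arrays. The covariance of the 2 late arrays was 0.729 against a simulated 0.0399, a difference of 0.689. Of the genes at least 2-fold from the reference, 374 were higher on both arrays, such as CIT1 and HSP12, where independent lists would share 62.7, and 389 were lower on both, such as RPS20 and NOP58, where independent lists would share 64.2. Part of this excess may come from the shared reference.

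Genes with large values midway and under 2-fold at 20.5 h were IMA5 at -6.28, STR3 at -4.19, YGL138C at -3.63, HST4 at -2.98 and GAT3 at -2.49, all at 15.5 h. None of the 5 passed the test for a change with glucose (limma adjusted p from 0.207 to 0.986). Each of them had 1 spot. STR3 and YGL138C were also low at 9.5 h, at -3.49 and -2.29, and at 0 h, at -1.32 and -1.67. IMA5 was at -1.60 at 9.5 h and -0.54 at 0 h, and GAT3 at -0.825 and -0.53. Without the 15.5 h array STR3 passed at 2.85 (adjusted p = 0.0127), YGL138C at 2.14 (adjusted p = 0.00243) and IMA5 at 1.45 (adjusted p = 0.0148), and GAT3 passed as higher too (adjusted p = 0.00366). The genes were picked for values that lay on that array, so leaving it out removes the outlying value by construction. These calls are therefore no evidence of a response to glucose.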

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

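The tests in this part were chosen after the result was seen, except 3 that were set before their results were seen: place on the array, for the 0 h genes and for the proteasome genes, and the scale of the late arrays.

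Probes with no gene symbol were used in no comparison. Of 682 such probes with a value on every array, 108 lay at least 2-fold from the reference at 18.5 h (27 higher and 81 lower) and 103 at 20.5 h (40 higher and 63 lower), against 2 at 0 h. These are 15.8% and 15.1% of the probes, where 23.6% and 22.4% of named genes lay as far, 572 higher and 561 lower at 18.5 h. What these probes measure is not known here, and no explanation was tested.

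The first pattern is that all 37 genes beyond 2-fold on the 0 h array, where both channels have the same label, were lower. Dim spots remain a candidate explanation: of genes with a blank on another array 16 of 639 were 2-fold lower, against 37 of 4807 without one, an odds ratio of 3.31 (Fisher's exact test, 2-sided p = 2.42e-04). For place on the array, 38 genes were lower after centring within runs of 40 probe IDs, which argues against a shift of most spots of a run. A smaller defect would hardly move the median of a run and would be left by this centring. Whether probe IDs follow the place on the array is not given in the sources used here, so place stays open. A reference further into the shift than the 0 h culture stays open: over the 5 consecutive steps from 9.5 h to 20.5 h the median of the 37 genes rose beyond random genes in 2, fell beyond them in 1 (-0.353 from 11.5 h to 13.5 h) and stayed within their range in 2, and it rose in the 4 longer spans looked at, which overlap these steps (by 0.955 from 13.5 h to 18.5 h). Lists disagree on it as well, since all 9 that passed as lower had 0 h medians above 0 and 3 of the 10 that passed as higher had medians below 0, which go with it, while the other 7 stood above 0, which does not. The trend fit includes the 0 h array, so lists whose 0 h medians go with it were more apt to pass, and their count is weak evidence. A difference between the RNA preparations of the 2 channels was not tested.

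The second pattern is the rise in genes beyond 2-fold at 18.5 h and 20.5 h. Noise of each late array alone is argued against, since 18.5 h less 15.5 h correlated with 20.5 h less 13.5 h across genes (r = 0.698, bootstrap over genes 0.678 to 0.716, and r = 0.718 with 13.5 h and 15.5 h exchanged), differences in which the shared reference cancels. The bootstrap treats genes as independent and leaves out the spread between arrays. An error common to the late arrays was not tested. For the centring of the late arrays, 1154 genes were beyond 2-fold at 20.5 h as deposited against 1077 after centring. The 2 settings differ by a shift of 0.185, which can hardly move a count over both directions, so this cannot decide the question. Any centring by the authors before deposit was not tested. For the trend, 1 of 100 orderings of the glucose values, the real one, gave as many as its 1849 genes, and the highest other gave 532. Neighbouring arrays of a time course are alike and cannot be exchanged freely, so these orderings cannot exclude chance. A response of the culture to the loss of glucose is a hypothesis these tests leave standing, but age and density of the culture and the array lot changed with it and cannot be told apart from it.

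The third pattern is that proteasome genes, as a list, were lower at 20.5 h than at 18.5 h by a median of -0.46. A different scale of the late arrays is argued against: after removing the slope between them (0.85) the list median was -0.35, outside the -0.23 to 0.16 that held the middle 95% of random lists. For place on the array, the median difference of the list was -0.50 after centring within runs of 40 probe IDs, which argues against a shift of whole runs. A smaller defect, or one that does not follow probe IDs, stays open. A passing rise near the exhaustion of glucose may account for it, as a hypothesis, and with 1 array per time point an error shared by these spots on 1 array stays open and was not tested. The fall was not particular to the proteasome list. Over the same step mitochondrial ribosomal protein genes had a median difference of -0.39 (46 of 52 lower) and antioxidant genes -0.52 (7 of 9 lower). Lists went both ways, and the respiratory chain median was 0.59 higher.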

How the results depend on the processing

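Leaving out the 0 h and 9.5 h arrays, and centring within runs of 40 probe IDs, were chosen after seeing the data. With an estimated correlation in camera 0 of the 24 lists passed (lowest adjusted p 0.154). At the preset correlation 10 or 11 lists passed as higher and 9 as lower with values as deposited, at least 5 values, hours, log2 OD, 2 glucose levels, robust fitting, runs of 40 and arrays left out, and lists were not tested in the other settings. The proteasome list passed as well with values as deposited, with 2 glucose levels, and without the 0 h, the 15.5 h, the 20.5 h or both the 0 h and 9.5 h arrays, and the hexose transport list with hours. Of the genes that changed with glucose, 0 took the other sign in any of these settings, which was not counted for spots tested alone. Where fewer arrays were used, the fits had fewer degrees of freedom. Elsewhere the cause was not tested. Blank cells and the lack of signal levels limit what can be said of dim spots.

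Genes risen and fallen numbered 936 and 913 and became 266 and 233 with hours, 597 and 512 with log2 OD, and 372 and 429 without the 0 h and 9.5 h arrays. Leaving out 1 array at a time gave 593 (without 18.5 h) to 1139 risen and 638 (without 18.5 h) to 1074 fallen. Of 109 named genes that passed, 54 did not with hours, 15 with log2 OD and 22 without the 0 h and 9.5 h arrays.

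Genes beyond 3 SD of the 0 h array in place of 2-fold numbered 69, 152, 95, 176 and 442 from 0 h to 15.5 h. Genes beyond 4-fold numbered 4, 9, 3, 7, 25, 194 and 243 over the 7 arrays. Relative to the 0 h array 58, 153 and 176 genes were beyond 2-fold at 9.5 h, 11.5 h and 13.5 h, and 58 at 9.5 h after centring within runs of 40 probe IDs. From 13.5 h to 18.5 h 696 were higher and 275 lower as deposited, and 51 and 22 at 4-fold. From 18.5 h to 20.5 h 18 were higher and 1 lower at 4-fold.

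Some fitted changes that had not passed took the other sign in some settings. HST4 (-0.02) became 0.16 as deposited, 0.42 with 2 levels and 0.33 without the 0 h and 9.5 h arrays, with a range of -0.68 to 0.44 leaving out 1 array. PIS1 (-0.06) became 0.12 as deposited, 0.11 with hours, 0.22 with log2 OD and 0.30 within runs of 40, with a range of -0.62 to 0.91. MIG1 (0.22) became -0.0719 with hours and -0.0542 with log2 OD, YAP1 (0.11) -0.0048 with hours, and IMA5 (0.45) -0.15 with log2 OD. Leaving out 1 array gave ranges of -1.07 to 1.45 for IMA5, -0.84 to 1.39 for IRC15, -2.07 to 0.15 for NOP2, -0.69 to 1.79 for PYC1 and -0.0698 to 0.26 for YAP1. Of these, without the 20.5 h array NOP2 passed as lower at -2.07 (adjusted p = 0.00204), IRC15 as lower at -0.84 (adjusted p = 0.0267) and PIS1 as higher at 0.91 (adjusted p = 0.0328).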

Other observations

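The genes and counts of this part were picked after their values were seen, and no test was run on them. Values on single arrays have no replicate.

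Some biosynthetic genes stood above the reference before glucose ran out and below it afterwards. The purine biosynthesis list, 9 genes, had medians of 0.36 at 13.5 h, 0.94 at 15.5 h and -0.63 at 18.5 h. ADE4, which encodes the first enzyme of the pathway, was at 0.94 at 15.5 h and -1.34 at 18.5 h, ADE1 at 1.19 and -0.40, ADE2 at 1.34 and -0.11, and ADE13 at 1.18 and -0.63. IMD2 and IMD3, which act on the branch to guanine nucleotides, were not part of this, at -0.08 and -0.13 at 15.5 h, nor was ADE8, at 0.53 at 15.5 h and 0.15 at 18.5 h. ADE6 was near the reference before its fall, at 0.02 at 13.5 h, 0.15 at 15.5 h and -1.44 at 18.5 h. HIS4, a histidine biosynthesis gene, was at 1.33 at 15.5 h and -0.31 at 18.5 h.

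Of the trend calls, 145 of the 936 genes that rose had a mean of -0.5 or lower over the 0 h and 9.5 h arrays, and 79 of these 145 were 2-fold higher on neither late array. Among the regulators HAP5 was such a gene, and among the peroxisomal genes POT1. Of the 913 that fell, 25 had a mean of 0.5 or higher on those arrays, and 12 of them were 2-fold lower on neither late array.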
